A study of Coturnix japonica and Phalacrocorax auritus with 29 samples.

How the data were processed

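The samples were 29 embryonic livers, 1 RNA-seq library per embryo, from Japanese quail (JQ) and double-crested cormorant (DCCO). Per the labels' protocols, solutions of chlorpyrifos, an organophosphate insecticide, or its solvent DMSO went into the air cell of fertilized eggs before incubation at 37 °C and 60% humidity. RNA was extracted from each liver and sequenced as paired reads of 101 bp on an Illumina HiSeq, per the same protocols. The labels give nominal doses of 0.4, 4 and 40 µg per g of egg for both species and do not tie them to the group names medium and high. They also say that the high dose was chosen from mortality data of each species.

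The deposited files hold 1 table of raw read counts per species, with 1 line per protein name, 22845 names for JQ and 21547 for DCCO. By the name of the deposited tables, the counts came from Seq2Fun with a database of all birds. Read settings, database version and any filter are not given in the sources used here, and no genome build applies, so no coordinates are printed. Per the submitters' processing notes edgeR was used, without a stated role or version. All values are whole numbers, and the totals per library ran from 11548222 to 27778954 counts in JQ and from 9890108 to 21976904 in DCCO. At such depths a feature at 1 CPM (counts scaled to depth) rests on about 10 or more reads per library. PCR reads are not independent molecules, so every interval and floor of counts covers counting error only.

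The tables name proteins, not gene symbols. Of the 1090 symbols in the gene and marker lists, 971 were matched to a protein name in JQ and 937 in DCCO, and 828 and 823 of these could be tested. Symbols printed for other features are the usual symbols of the protein names. Reads of near-identical proteins (the CYP2, CYP3A and UGT1 families above all) can be shared out among similar names by this kind of counting, so values of single family members are uncertain.

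Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr at its defaults (a count of 10, a total of 15), and the robust quasi-likelihood test on group means. All 15 JQ libraries were fitted together and all 14 DCCO libraries together, so the 3 groups of a species share 1 estimate of the spread. A feature was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 14927 features tested in JQ or the 14579 in DCCO. Standard errors are the log2 fold change divided by the square root of the F statistic of that test. CPM values are TMM-normalised unless said otherwise, with SD over libraries. The labels present the replicates as separate embryos, and the p-values measure the spread between these samples.

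Species were compared with 1 fit of all 29 libraries on 15596 names that occur in both tables, by the contrast of the JQ dose effect minus the DCCO dose effect. Overlap of calls used Fisher's exact test, one-sided. Overlap of the doses, which share control libraries, was set beside 20 simulations of unchanged groups, the overlap of independent lists and splits of the controls.

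There were 20 gene lists of liver functions and toxic responses, fixed by symbol, each needing 5 tested members. Each was tested with camera in limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists of a comparison, and again with an estimated correlation and with fry. Counts of changed members are given over all features and adjusted over the list alone. Marker lists of cell types, other tissues, ribosomal proteins and chromosome Z were scored per library as mean log2 CPM (prior count 2) and compared with exact permutation tests, two-sided, over 252 arrangements in JQ and 126 for DCCO against control.

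Groups, tests, lists, markers, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule the text names the 10 features with the largest rise and the 10 with the largest fall at the high dose (5 each at the medium dose) among changed features with a gene symbol and an average log2 CPM of at least 0. Where fewer than 5 passed, it names all of them and the smallest p up to 5. It also names up to 4 members with the smallest p of each list spoken of, 5 features per direction for the species difference, and esterase, paraoxonase, CYP1A, CYP2 and CYP3A genes whenever tested. Protein names that end in "like" or are uncharacterised were taken as having no symbol. Some features that the rule covers are not reported here.

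The alternatives fixed at the outset were relative log expression size factors, no filter on low counts, DESeq2 1.42.0, limma voom, a block for the replicate number, Z-linked gene level as a covariate for embryo sex, a 1.5-fold minimum, fits of only the groups compared, leave-one-out and, for the species, separate voom fits joined by a z test. Chosen after seeing the data were fits without the 3 JQ libraries with markers of other tissues, without the 2 DCCO libraries with number 6 in the column name, with that number as a factor, and with each name and its like name summed.

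The procedure was tested on simulated counts with 200 planted changes, 100 of them 2-fold and 100 4-fold. Of the 2-fold changes it called 56% for JQ high dose, 61% for JQ medium dose, 69% for DCCO high dose and 72% for DCCO medium dose. Of the 4-fold changes it called 89%, 91%, 93% and 94% in the same order. For the species difference it called 45% and 83% at the high dose and 39% and 80% at the medium dose.

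One DCCO control column carries a number that matches no numbered control label, so it is called the unnumbered control; its group is clear. All 29 libraries were kept.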

Results

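Messenger RNA was measured in embryonic livers of a galliform species, the Japanese quail (JQ), and a seabird, the double-crested cormorant (DCCO). The series title asks how these species differ in their sensitivity to chlorpyrifos. JQ had 5 control, 5 medium dose and 5 high dose libraries, and DCCO had 4, 5 and 5. The labels give embryo day 9 for JQ, except for control replicate 5, which they give as day 16, and day 16 for DCCO. Totals per library ran from 11548222 to 27778954 counts in JQ and from 9890108 to 21976904 in DCCO. The leading principal component held 22% of the variance in JQ, where all 5 high dose libraries lay on one side of it and the other 10 on the other side. In DCCO it held 25.7% and set control replicate 1 and high dose replicate 1 apart from the other 12 libraries, not the doses.

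The high dose in JQ raised the cytochrome P450 genes of xenobiotic oxidation by up to 3 orders of magnitude. CYP2H1 rose from 3.39 ± 2.42 CPM in controls to 6908 ± 2099 CPM (SD, n = 5 each), and CYP2H2 from 3.20 ± 2.14 to 4344 ± 1239 CPM. ALAS1, which encodes the enzyme that starts heme synthesis, rose from 116 ± 32.8 to 2298 ± 674 CPM. CYP2C18, CYP2C19, CYP3A37 and the feature named cytochrome P450 3A8 rose too, by log2 fold changes of 4.89 to 6.34. The aryl hydrocarbon responsive genes CYP1A1, CYP1A4 and CYP1A5 rose by 2.78, 2.52 and 2.62. Each of these genes was above every control in 5 of 5 high dose libraries. The log2 fold change was 11.02 ± 0.73 (SE) for CYP2H1 with an adjusted p of 4.9e-07, 10.44 ± 0.59 for CYP2H2 and 4.30 ± 0.25 for ALAS1, each with 7.4e-08, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CYP2C23B stood at 47.2 ± 14.5 CPM against 3 reads over all controls, a ratio of 1363 with a 95% counting interval of 466 to 6611. CYP2W1 rose by 1.45 and CYP2W2 by 1.24, and the call of CYP2W2 ended without any 1 of control replicates 1, 2, 4 and 5, medium dose replicate 4 and high dose replicates 1, 3 and 4, at adjusted p of 0.0501 to 0.0937. CYP2K6, CYP2AC1, CYP2AC2 and CYP2R1 changed by -0.33, -0.24, -0.11 and 0.03, with adjusted p of 0.794 or more. Reads may be split among similar CYP2 names, so the share of each member is uncertain.

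**Figure D1:**
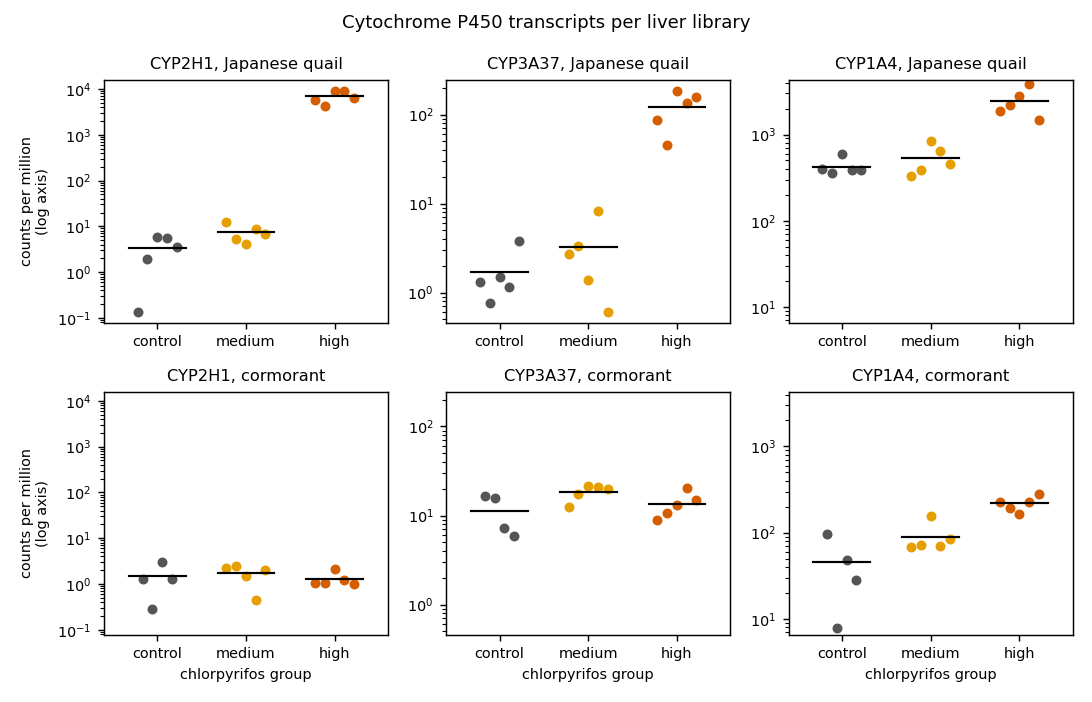
CPM of CYP2H1, CYP3A37 and CYP1A4 in each liver library (points) by chlorpyrifos group, with group means (lines), on a log axis, JQ above and DCCO below. In JQ, CYP2H1 averaged 6908 CPM at the high dose and 3.39 CPM in controls, and in DCCO 1.29 and 1.47 CPM.

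Single genes of conjugation and transport rose in JQ as well, beside antioxidant genes. The feature named UDP glucuronosyltransferase 1-6 rose from 0.480 ± 0.190 to 30.6 ± 12.8 CPM, UGT1A1 by a log2 fold change of 1.30, and HPGDS, a glutathione transferase, by 2.87. The efflux pumps ABCB4, ABCB1 and ABCC2 rose by 1.53, 1.28 and 0.70, and the heme and iron carriers SLC25A39 and SLC11A2 by 0.60 and 0.77. The antioxidant genes OSGIN1 and GCLC rose by 1.55 and 1.26, and PPARG and ELOVL5 of the fatty acid and triglyceride synthesis list by 1.73 and 1.92, while GPAM fell by 0.61. All of these were called changed, with adjusted p of 0.0172 or less, by edgeR with Benjamini-Hochberg adjustment. The call of GPAM ended without the 3 libraries with markers of other tissues (0.0786), a fit chosen after seeing the data. KEAP1, the sensor of oxidative stress, rose by 0.40 and ferritin heavy chain (FTH1) by 1.0, with adjusted p of 0.0185 and 0.0211. These calls ended without control 1 for KEAP1 (0.0513) and without control 1, 2 or 5 for FTH1 (0.0623, 0.0545 and 0.0509). The largest other rises were a gastrin and cholecystokinin-like peptide (8.14), TMEM139 (6.02), TPPP (5.82) and SLC34A1 (6.25), a phosphate carrier of the kidney. The peptide and TMEM139 varied widely at the high dose (85.7 ± 102 and 11.9 ± 11.7 CPM), with log2 fold changes of 7.31 to 9.01 and 5.26 to 6.38 over all alternatives. Limma voom called neither (0.234 and 0.111), nor SLC34A1 (0.218). SLC34A1 reached 1425 CPM of the library total in high dose replicate 1 and at most 31.0 CPM in any other JQ library. Its log2 fold change was 2.46 without that replicate, and its call ended without any 1 of control replicates 1, 2, 4 and 5, at adjusted p of 0.0508 to 0.0636.

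Complement C3 and NR0B1 were among the genes with the largest falls in JQ. Complement C3 fell from 924 ± 520 to 76.6 ± 26.5 CPM (n = 5 each) and lay below every control in 5 of 5 libraries, with a log2 fold change of -3.59 ± 0.64 and an adjusted p of 0.00612 (edgeR). The orphan nuclear receptor NR0B1 fell by 2.96, the activin subunit INHBA by 2.88 and CCDC69 by 3.38. Control 1 carried part of the size for CCDC69 (16.4 CPM, control mean 5.72): without it the log2 fold change was -2.46, and limma voom did not call it (0.0927). Plasminogen (PLG) fell by 0.94 and prothrombin (F2) by 0.54, while APOA5 rose by 1.2, a call that ended with only the 2 groups in the fit (0.0504). The interferon-induced kinase EIF2AK2 fell by 1.23, and HELZ2, ZNFX1 and STAT2 of the same response by 0.67, 1.77 and 0.56, which were not called (adjusted p 0.0619 to 0.0683). Falls of ABCA13 (-6.25), GM2A (-3.31), SRL (-2.81), CALHM3 (-2.80) and PIK3C2G (-2.77) passed with adjusted p of 0.0223 to 0.0314 and each lost its call, at adjusted p of 0.0507 to 0.0810, when single libraries were left out. These were control 5 and high dose 1, 3, 4 and 5 for ABCA13, high dose 3, 4 and 5 for GM2A, controls 1 and 5 and high dose 5 for CALHM3, controls 1 and 5 and high dose 3, 4 and 5 for PIK3C2G, and controls 2, 3 and 5 and high dose 2 to 5 for SRL. Control 1 also carried much of the size for GM2A, at 357 CPM against a control mean of 102, and without it the log2 fold change was -1.88. Limma voom called none of these 5 (0.0893 to 0.596). The call of F2 ended likewise without control 1, 3, 4 or 5 or high dose 3 or 5 (0.0504 to 0.0722).

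The esterases that react with organophosphates changed little at the transcript level in JQ. PON2 fell by 0.49 and PON1 by 0.51, with adjusted p of 0.0501 and 0.0683, and BCHE changed by -0.24 (0.346, edgeR). Hepatic lipase (LIPC) fell by 0.60, a call (0.0356) that ended without control 1, 3, 4 or 5 or high dose 3, at 0.0534 to 0.0936, and FAAH rose by 0.41 (0.0683). Without medium dose replicate 1 or high dose replicates 2 or 4 PON2 passed (0.0478, 0.0204 and 0.0442), and PON1 passed without control replicate 2 (0.0329). With a 1.5-fold minimum neither passed, but that setting can only remove calls and neither was called without it, so it decides nothing here. DESeq2 gave the smallest values over the alternatives, 0.0116 and 0.0238. ACHE had too few counts to be tested in JQ, and no feature name matched CES1 in either species.

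In all, the high dose changed 531 of 14927 JQ features, 316 up and 215 down, and 2479 had an unadjusted p under 0.05. Leaving out single libraries gave 303 to 659, with 303, 347, 309 and 340 without control 1, 2 or 4 or high dose 5. Of the 20 gene lists, camera called 4. For xenobiotic oxidation 16 of 26 members rose, also when adjusted over the list alone, and the list's adjusted p was 4.2e-23. For antioxidant and glutathione genes 7 of 37 rose (12 rose and 1 fell adjusted over the list alone) with 7.6e-05. Both calls held with an estimated correlation, at adjusted p of 0.00360 and 0.00707. Plasma proteins (1 up and 5 down of 46; 3 up and 17 down adjusted over the list alone; 1.5e-07) and interferon response genes (1 down of 25; 7 down adjusted over the list alone; 0.00165) were called lower at the preset correlation only, with 0.425 and 0.731 when it was estimated. Conjugation genes (3 up of 19, 4 adjusted over the list alone; camera 0.192) had a median of -0.01 against a mean of 0.38 and an upward test. Bile acid genes (4 up and 2 down of 29, 6 and 4 adjusted over the list alone; 0.820) had a median of -0.05 against a mean of 0.10 and an upward test. Esterases (1 down of 23; 2 up and 3 down adjusted over the list alone) gave 0.282.

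Among markers of cell types in JQ at the high dose, the mean log2 CPM of hepatocyte markers was lower by -0.42 and that of bile duct (cholangiocyte) markers higher by 0.59. Each had an exact permutation p of 0.00794, the smallest that 252 arrangements can give two-sided, and 0.0556 after adjustment over 14 marker lists, so neither passed this test. With only 2 lists at that smallest p the adjusted value cannot fall below 0.0556, so this says little against either. Camera called both, with adjusted p of 0.00123 and 0.0180, and neither with an estimated correlation (0.737 and 0.235), and fry called the bile duct list (0.0178) and not the hepatocyte list (0.164). SPP1 of the bile duct list rose by 2.53. Erythroid, macrophage, endothelial and stellate markers differed by 0.03, -0.04, -0.06 and -0.07, ribosomal proteins by 0.15 and Z-linked genes by 0.02, with exact permutation p of 0.111 or more. The macrophage mean includes HPGDS, which rose by 2.87, and the median log2 fold change of that list was -0.26. CSF1R, C1QA and MARCO, next in p, changed by -0.60, -0.67 and -0.65 and were not called. Camera called ribosomal proteins, a sign of RNA quality, higher (0.000293), and not with an estimated correlation (0.836) or by fry (0.396).

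The medium dose in JQ left the liver transcriptome without a called change. The smallest p-values belonged to PLPP4 (-1.53), TRAF1 (2.06), FRRS1 (-0.79), VCAM1 (2.84) and FNIP2 (-0.72), all with an adjusted p of 0.603. CYP2H1 averaged 7.51 ± 3.36 CPM (n = 5) and CYP2H2 6.51 ± 3.39 CPM, and their log2 fold changes of 1.18 and 1.06 did not pass (adjusted p 0.999, edgeR). The other CYP1A, CYP2 and CYP3A genes tested changed by -0.16 to 0.95, and BCHE, PON1 and PON2 by -0.10, -0.08 and -0.10. Interferon response genes, led by IFI6 (-3.60), IRF1 (-0.86), STAT2 (-0.48) and EPSTI1 (-1.99), were the 1 gene list called by camera (adjusted p 0.00025). They were not called with an estimated correlation (0.837). Of 25 members 0 changed, and 5 fell adjusted over the list alone. IFI6 varied widely in controls (36.0 ± 46.5 CPM, from 1.72 to 105). Below every control lay 1 of 5 medium dose libraries for IFI6, 3 for IRF1, 3 for STAT2 and 0 for EPSTI1. Camera also called macrophage markers lower (0.0148) and erythroid (0.0148), gut (0.0201), stellate and muscle markers (0.0203 each) higher, none with an estimated correlation (0.284 or more) or by exact permutation (smallest p 0.0317, for gut; 0.444 adjusted). The test by edgeR called 0 of 14927 features, with 646 at an unadjusted p under 0.05. DESeq2 called 6 and limma voom 0. With the same tool, 61% of planted 2-fold changes were called.

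Xenobiotic oxidation and antioxidant genes were higher at the high than at the medium dose in JQ. Of 26 xenobiotic oxidation genes 16 were called higher (16 adjusted over the list alone), and 3 of 37 antioxidant genes (11 higher and 1 lower adjusted over the list alone). By edgeR 282 features differed, 206 higher and 76 lower, with 1998 at an unadjusted p under 0.05. Without medium dose 2, 3, 4 or 5 or high dose 3 the count was 174, 168, 166, 181 or 180. Camera gave adjusted p of 5.9e-30 and 0.000155 for these lists, and 0.00109 and 0.00946 with an estimated correlation. It called 6 more lists at the preset correlation only: plasma proteins (1.0e-05), conjugation (0.00836), oxidative phosphorylation (0.0217), fatty acid synthesis (0.0297), cell cycle (0.0348) and cholesterol synthesis (0.0477). Camera also called bile duct markers and ribosomal proteins higher and hepatocyte and stellate markers lower (0.0077 each). Erythroid, muscle (0.0127 each) and granulocyte and thrombocyte markers (0.0129) were called lower. No marker list passed with an estimated correlation (0.155 or more) or by exact permutation (adjusted 0.111 or more). Fry called the bile duct list alone (0.0224).

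The genes called at the high dose in DCCO encode RNA-binding, signalling and co-chaperone proteins, and edgeR with all libraries called no drug metabolism gene, while DESeq2 and the fit without control 1 called CYP1A4 and CYP1A5. RSRP1, an arginine- and serine-rich nuclear protein, rose from 6.03 ± 1.38 CPM (SD, n = 4) to 24.3 ± 3.90 CPM (n = 5). The splicing factor RBM5 rose from 66.5 ± 5.23 to 148 ± 14.8 CPM. The cold-inducible RNA-binding protein CIRBP fell from 256 ± 24.8 to 166 ± 18.2 CPM and the phosphatase DUSP4 from 60.8 ± 6.77 to 39.5 ± 3.88 CPM. Each lay outside the control range in 5 of 5 high dose libraries. Log2 fold changes were 2.0 ± 0.17 for RSRP1 and 1.15 ± 0.10 for RBM5, each with an adjusted p of 2.3e-05 by edgeR's quasi-likelihood test, and -0.63 ± 0.10 for CIRBP and -0.62 ± 0.10 for DUSP4, each with 0.0392. A co-chaperone feature named DNAJA1-like rose by 1.01 (0.0392); it falls outside the naming rule and was chosen after its values were seen. Histone H1.01 (-0.90) came next and was not called by edgeR (0.0744), while limma voom (0.0483) and DESeq2 (0.000199) called it.

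**Figure D2:**
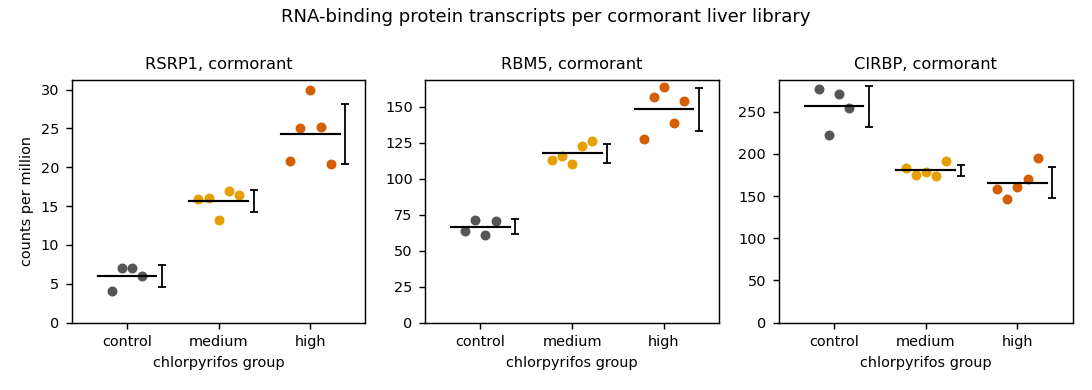
CPM of RSRP1, RBM5 and CIRBP in each DCCO liver library (points) by chlorpyrifos group, with group means (lines) and SD (bars at the side), on axes from 0. RBM5 averaged 66.5 CPM in 4 controls, 118 CPM in 5 medium dose and 148 CPM in 5 high dose libraries.

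The calls of CIRBP, DUSP4 and DNAJA1-like in DCCO were near the threshold. They ended without any 1 of 12, 12 and 11 of the 14 libraries, at adjusted p of up to 0.185, 0.185 and 0.178. CIRBP stayed called only without control replicate 2 or high dose replicate 5, DUSP4 only without the unnumbered control or high dose replicate 1, and DNAJA1-like only without control replicate 1 or high dose replicates 1 or 5. The calls of RSRP1 and RBM5 held in every fit with a library left out. Control libraries carried one prefix in their column names and all exposed DCCO libraries another, so a batch with that name cannot be told apart from exposure in this species.

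Among drug metabolism genes of DCCO, CYP1A4 stood at 220 ± 45.2 CPM at the high dose and 45.2 ± 38.1 CPM in controls, and CYP1A5 at 150 ± 27.2 and 38.8 ± 36.7 CPM. Both were above every control in 5 of 5 libraries, and neither passed, with log2 fold changes of 2.28 and 1.95 and adjusted p of 0.187 and 0.315 (edgeR). Without control replicate 1 they were 2.97 and 2.83 and passed, with 0.0431 and 0.0399, and DESeq2 called both (0.00917 and 0.0488). Over all alternatives their adjusted p ran from 0.00917 to 0.888 and from 0.0399 to 0.914. CYP2AC1 and CYP2W1 had log2 fold changes of 1.05 and 0.53 and were not called (0.326 and 0.837). CYP2H1, CYP2C19, CYP2W2, CYP2R1, CYP2J2, CYP3A37, CYP2K6, CYP2G1 and CYP3A9 changed by -0.22, -0.25, -0.04, 0.08, 0.18, 0.26, 0.41, 0.41 and 0.52, and ALAS1 by 0.06. ACHE had a log2 fold change of -0.90, was not called (adjusted p 0.404) and was below every control in 5 of 5 libraries, while BCHE, PON1 and PON2 changed by -0.05, -0.04 and -0.07. The bile acid receptor NR1H4 (0.58, adjusted p 0.0744) and the heat shock genes BAG3 (0.77, 0.0864) and DNAJA4 (0.60, 0.166) were not called by edgeR, and DESeq2 called each (0.000199, 0.000420 and 0.00604).

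The DCCO high dose changed 5 of 14579 features, 3 up and 2 down, by edgeR, and 777 had an unadjusted p under 0.05. DESeq2 called 60 and limma voom 6. The fit without control 1 and high dose 1, the libraries with number 6 in the column name, called 16 and was chosen after seeing the data. The count was 14 without control 1 and 8 without high dose 1, and 2 or 3 without control 3, the unnumbered control, any medium dose library or high dose 2, 3 or 4. Camera called xenobiotic oxidation (0 of 24 changed, 3 up adjusted over the list alone) and bile acid genes (0 of 29, 1 up), each higher with an adjusted p of 0.0250, and neither with an estimated correlation (0.485). The xenobiotic oxidation list's median was 0.03 and its mean 0.27. Heat shock genes gave 0.0511 (2 up adjusted over the list alone). Erythroid markers were higher by 0.62 in mean log2 CPM (exact permutation p 0.0635, 126 arrangements, two-sided; 0.952 adjusted). Camera called them (7.8e-09; 0 of 16 members changed, 4 up adjusted over the list alone), and not with an estimated correlation (0.226) or by fry (0.260). At the medium dose they were higher by 0.38 (exact permutation p 0.167; camera 0.0131, 0.951 with an estimated correlation). At this size, 69% of planted 2-fold changes and 93% of 4-fold changes were called.

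The medium dose in DCCO raised RSRP1 and RBM5 and lowered G0S2, SRSF5 and DUSP4. RSRP1 rose to 15.7 ± 1.43 CPM and RBM5 to 118 ± 6.66 CPM (n = 5). G0S2, an inhibitor of fat breakdown, fell from 117 ± 31.4 to 38.3 ± 6.86 CPM, and the splicing factor SRSF5 from 130 ± 23.9 to 74.2 ± 3.41 CPM. DUSP4 fell by 0.76. Each lay outside the control range in 5 of 5 libraries. The log2 fold changes by edgeR were 1.37 ± 0.17 for RSRP1 and 0.82 ± 0.10 for RBM5 (adjusted p 0.00285 each), -1.61 ± 0.20 for G0S2 (0.00338), -0.81 ± 0.11 for SRSF5 (0.00648), and -0.76 ± 0.10 for DUSP4 (0.00410). A lipid droplet feature named cell death activator CIDE-3-like fell by 1.45 (0.0265), outside the naming rule and chosen after its values were seen. Its call ended without any 1 of 9 libraries, at adjusted p of up to 0.128: controls 1, 2 and the unnumbered one, medium dose 1 to 5 and high dose 4. CIDEC of the same family fell by 1.32 (0.0603) and passed without control 3 or high dose 1 or 5 (0.0332, 0.00107 and 0.0311; 0.000180 to 0.782 over all alternatives).

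Other DCCO medium dose values pointed down in metabolic genes without passing. CHAC1 fell by 2.29 (adjusted p 0.0713), MTHFD2 by 1.07 (0.106), PDK4 by 1.75 (0.359) and ANGPTL4 by 0.67 (0.169, edgeR). Without the unnumbered control or high dose replicate 1, CHAC1 (0.0104 and 0.0333) and MTHFD2 (0.0239 and 0.0491) passed. Over all alternatives the adjusted p of these genes ran from 0.000140 to 0.401 and from 0.00114 to 0.437. CYP1A4 and CYP1A5 changed by 1.0 and 0.46, CYP3A9 by 1.13, CYP2AC1 by 0.98 and the other CYP2 and CYP3A genes by -0.50 to 0.70, with adjusted p of 0.435 or more. ACHE, BCHE, PON1 and PON2 changed by -0.40, -0.42, -0.30 and -0.19. In all, 7 of 14579 features changed, 2 up and 5 down, and 833 had an unadjusted p under 0.05. DESeq2 called 52 and limma voom 7, and without high dose 1 the count was 16. Camera called 8 lists lower: oxidative phosphorylation (5.6e-08), conjugation and endoplasmic reticulum stress (0.000626 each), glycolysis (0.00119), fatty acid oxidation (0.00151), fatty acid synthesis (0.0379), and cholesterol synthesis and nitrogen catabolism (0.0460 each). None held with an estimated correlation, where the smallest adjusted p was 0.274. Of their members, 1 changed (G0S2), and 9 fell adjusted over the list alone: 3 of fatty acid synthesis, 3 of fatty acid oxidation, 2 of endoplasmic reticulum stress and 1 of conjugation.

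No gene passed the adjusted threshold between high and medium dose of DCCO by edgeR. RSRP1 and RBM5 were higher at the high dose by 0.63 ± 0.15 and 0.33 ± 0.09, with unadjusted p of 0.00054 and 0.0021. So were DNAJA1-like by 0.47 (0.0052), G0S2 by 0.81 ± 0.19 (0.00068) and CIDE-3-like by 0.85 ± 0.22 (0.0015). G0S2 and CIDE-3-like, lowered by 1.61 and 1.45 at the medium dose, thus lay nearer control at the high dose. There they changed by -0.80 and -0.60 and SRSF5 by -0.60, with adjusted p of 0.315, 0.827 and 0.0866 (edgeR). By edgeR 0 of 14579 features differed at an adjusted p under 0.05, with 475 at an unadjusted p under 0.05. DESeq2 called 2 and limma voom 0. Camera called oxidative phosphorylation (1.4e-10), fatty acid oxidation (0.00028), conjugation (0.000803), cholesterol synthesis (0.00993) and nitrogen catabolism (0.0198) higher and cell cycle genes (0.000803) lower, none with an estimated correlation (0.505 or more). Erythroid markers were called higher too by camera (0.0113). They were not called with an estimated correlation (0.611), by fry (0.859) or by exact permutation (p 0.262).

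Genes changed at both doses were 0 in JQ and 3 in DCCO: RSRP1 and RBM5 up and DUSP4 down. For DCCO, 20 simulations of unchanged groups against the same controls gave a mean of 0.05 shared features and at most 1, and independent lists would share 0.000412 up and 0.000686 down. Neither holds a difference between the column name prefixes, which set the DCCO controls apart from all exposed libraries. Such a difference could put the same features in both lists, so the overlap cannot tell exposure from prefix. With the controls split between the doses in 6 ways, the mean was 0.833 and the range 0 to 2. Across features, which are not independent replicates, log2 fold changes of the doses had a covariance of 0.0751 in JQ against 0.0466 in simulation, and of 0.0472 against 0.0434 in DCCO. The correlations were 0.409 (simulated 0.510) and 0.627 (simulated 0.562). For DCCO, DESeq2 shared 23 features and limma voom 3. For JQ, DESeq2 shared 3 features, and limma voom called 0 at the medium dose.

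At the high dose the smallest p-values of the species difference belonged to CYP2 genes and ALAS1, which rose in JQ. The log2 fold change in JQ exceeded that in DCCO by 12.49 ± 0.75 for a feature named CYP2H1-like, 11.25 ± 0.90 for CYP2H1, 5.25 ± 0.52 for CYP2C19, 5.04 ± 0.51 for CYP2C19-like and 4.24 ± 0.31 for ALAS1. In the other direction, PPP1R3B, a regulator of glycogen, differed by -3.74 ± 0.56, FNIP2 by -1.74 ± 0.27, PLEKHA6 by -1.35 ± 0.20, RBM5 by -1.31 ± 0.21 and ASB3 by -1.08 ± 0.18. RBM5 changed by -0.15 in JQ and 1.15 in DCCO. All of these had an adjusted p of 0.000861 or less by edgeR's interaction test over 29 libraries. It called 188 of 15596 features, 118 more raised in JQ and 70 less, with 1841 at an unadjusted p under 0.05. For CYP1A4 and CYP1A5, above every control in both species, the difference was 0.24 ± 0.57 and 0.67 ± 0.56 and did not pass (0.943 and 0.727). Embryo day, the dose behind each group name and the batches of the species may differ as the species do, so these differences cannot be ascribed to species alone. The column name prefix that sets DCCO controls apart from exposed DCCO libraries does not cancel in this contrast. It bears most on differences that rest on the DCCO change, such as RBM5 and ASB3 (-0.27 in JQ and 0.81 in DCCO).

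At the medium dose the species difference called 0 of 15596 features by edgeR, with 1030 at an unadjusted p under 0.05, while DESeq2 called 21 and separate voom fits with a z test 18. Among the smallest p-values were those of the calcium-binding carrier SCaMC-2 (1.67), RBM12B (-0.70), CHAC1 (2.68) and EVI5 (-0.72), with adjusted p of 0.0961 to 0.140.

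No gene was called in both species at the high dose. Among 12355 features tested in both, 256 rose in JQ and 3 in DCCO, and 185 and 2 fell, with 0 shared in either direction (Fisher's exact test, one-sided, p 1 each; 0.0622 and 0.0299 expected of independent lists). At an adjusted p under 0.1 the shared count was 0 as well, and DESeq2 shared 5. Across these features the log2 fold changes of the species had a Pearson r of 0.0129 and a Spearman rho of -0.0401; features are not independent replicates.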

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

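The tests of kidney transcripts, of cell type shares and of the prefix of the column names were chosen after the result was seen. In 27 of 410 groups of 4 to 5 libraries 1 library lay far from the others by Dixon's ratio, its gap over the range of its group, where chance alone gives about 1 in 20, or 20.5.

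In JQ high dose replicate 1 stood out as highest for SLC34A1 (gap 0.776 of the range), GCLC (0.729) and the kidney and gonad markers (0.889), and as lowest for C3 (0.911) and LIPC (0.711). In the same group replicate 2 was lowest for PIK3C2G (0.757), replicate 3 highest for FTH1 (0.768) and replicate 5 lowest for granulocyte and thrombocyte markers (0.855). Among JQ controls, replicate 2 was highest for KEAP1 (0.884) and lowest for F2 (0.954), replicate 3 highest for CYP1A1 (0.717) and CYP1A4 (0.809) and lowest for Z-linked genes (0.787), and replicate 5 highest for CYP2AC2 (0.820). JQ medium dose replicate 2 was lowest for IFI6 (0.846).

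In DCCO, high dose replicate 3 was highest for CYP2H1 (0.719), replicate 4 highest for BCHE (0.821) and replicate 1 lowest for stellate and fibroblast markers (0.780). Control replicate 2 was lowest for CYP2J2 (0.946) and lymphocyte markers (0.874), and control replicate 1 highest for Z-linked genes (0.872). Medium dose replicate 3 was lowest for RSRP1 (0.738) and highest for CYP1A4 (0.729), replicate 1 highest for SRSF5 (0.792) and lowest for CYP2W1 (0.819), and replicate 5 lowest for SULT1E1 (0.741) and MTHFD2 (0.718).

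JQ high dose replicate 1 carried kidney transcripts: SLC34A1 stood at 1425 CPM of its total against at most 31.0 in other JQ libraries, LRP2 at 558 against 46.3 and CUBN at 327 against 1.33. A response to the dose stays open: in the other 4 high dose libraries the median log2 ratio to control over the tested kidney and gonad markers was -0.30, but these went both ways, SLC34A1 by 2.38 and SLC12A1 by -5.17. Kidney tissue in the library may be the source and stays open too: 6 of 14 such markers were highest in it, under the share of 0.5 set as the bound.

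The P450 and ALAS1 rise in JQ did not rest on that library: without it the median log2 fold change of the 16 called members was 3.59 against 3.54 with it. Reads shared between a name and its own like name are argued against as the cause, since with these summed 16 of 16 were still called. That sum leaves different family members, such as CYP2H1 and CYP2H2, apart and changes nothing for a member without a like name. Sharing of reads among family members was therefore not tested. A higher share of another liver cell type is argued against as the whole cause, since the highest median among 6 such marker lists was 0.41 (bile duct, SD of members 0.86), far below 3.54, by a bound set when these medians were known. A smaller shift from hepatocytes to other cell types stays open. Hepatocyte markers, which but for HNF4A are plasma protein genes, were lower on average, and bile duct markers were higher. HNF4A itself rose by 0.74 and APOA1 by 0.44. Adjusted over the hepatocyte list alone, 2 members rose and 7 fell. The medians of 4 of 4 other lists were below 0 (endothelial -0.01, stellate -0.08, erythroid -0.12, macrophage -0.26). They lie too near 0 to decide, so the bound set for them was wrong. A response of liver cells to the high dose is a hypothesis that these tests leave open.

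RBM5 and RSRP1 rose and CIRBP fell in exposed DCCO, whose libraries carry another prefix in their column names than the controls. Within one prefix RBM5 was higher at the high than the medium dose by 0.33 ± 0.09 and RSRP1 by 0.63 ± 0.15 (edgeR, unadjusted p 0.00207 and 0.000538). The prefix alone would not give such a difference. Yet both genes were picked for their rise at the high dose, and the same high dose libraries enter here. That choice favours a difference, and no feature passed adjustment (smallest adjusted p 0.796). The prefix as the whole cause of their rise therefore stays open. For the 9 called features together, exposure and prefix cannot be told apart: 5 differed between the doses at an unadjusted p under 0.05, which passes the share of 0.5 set as the bound, yet 3 of the 5 were called at one dose only, so the bound was wrong, and CIRBP did not differ (p 0.224). The number in the column name is argued against for RBM5, whose log2 fold change was 1.07 with it as a factor and 1.15 without. A difference in temperature could lower CIRBP and stays open, since RBM3, another cold-induced gene, changed by 0.052 ± 0.29.

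The species differed at the high dose, by the interaction test of edgeR over 29 libraries, for CYP2H1-like (12.49), CYP2H1 (11.25), CYP2C19 (5.25), CYP2C19-like (5.04), ALAS1 (4.24), ASB3 (-1.08), RBM5 (-1.31), PLEKHA6 (-1.35), FNIP2 (-1.74) and PPP1R3B (-3.74). All of these calls held in the 38 alternatives run for them.

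Chance is argued against, and not excluded, where the true grouping called more features than any other split drawn. This held for JQ high dose (531 features, at most 2 in the other splits, 1 of 100 splits called as many). It held for JQ high against medium dose (282, at most 29, 1 of 100) and DCCO medium dose (7, at most 1, 1 of 100). It held for the species difference at the high dose (188, at most 0, 1 of 50). For DCCO high dose the margin was small (5, at most 3, 1 of 100). The split that called as many was the true grouping itself. Other splits mix exposed and control libraries, so a real effect widens their spread and can lower their counts. Where edgeR called 0 the splits say nothing about chance, since every split calls at least 0: JQ medium dose (646 at an unadjusted p under 0.05, DESeq2 6, limma voom 0; at most 2 in other splits; 100 of 100), DCCO high against medium dose (475, DESeq2 2, limma voom 0; at most 2; 100 of 100) and the species difference at the medium dose (1030, DESeq2 21, z test 18; at most 0; 50 of 50).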

How the results depend on the processing

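The settings without the libraries that held other-tissue markers or the number 6, with the column number as a factor and with like names summed were chosen after seeing the data. No result reversed. JQ P450 and ALAS1 calls other than CYP2W2 held in all 25 alternatives, as did RSRP1 and RBM5 at the DCCO high dose.

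DESeq2 called more than edgeR: JQ high dose 976 (527 shared with the 531), JQ medium dose 6, JQ high against medium dose 627 (280), DCCO high dose 60 (5), DCCO medium dose 52 (7), DCCO high against medium dose 2, species difference 363 (185) at the high and 21 at the medium dose, and 5 features shared by species, 3 by JQ doses and 23 by DCCO doses. The z test on separate voom fits called 370 (177) and 18. Fitting only the groups compared gave 128 (124) for JQ high against medium dose and 2 for DCCO high dose. No filter on low counts gave 3 for DCCO high dose, the column number as a factor 3 (2 shared) and, for DCCO high against medium dose, 1. Without the number 6 libraries DCCO high dose gave 16 (5) and the DCCO doses shared 5. Split controls gave a mean of 0.833 shared. The cause was not tested, except that fewer samples enter where groups or libraries are left out.

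Replicate numbers as blocks gave 187 (170 shared) for JQ high against medium dose, 2 for DCCO high dose, 1 for DCCO medium dose, 94 (82) for the species difference and 0 shared by DCCO doses. Libraries of the same number had a mean residual correlation of 0.001 in JQ and 0.138 in DCCO. In DCCO the 11 pairs ran from -0.119 to 0.385, not all over 0.1, so the numbers were not taken to pair samples, though a partial pairing is not excluded. With the block the DCCO medium dose calls of RSRP1, RBM5 and DUSP4 (adjusted p 0.0509 each) and SRSF5 (0.0510) ended, at log2 fold changes of 1.39, 0.83, -0.82 and -0.82, so this is not a weaker effect.

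Gene lists called by camera were 4, 1, 2 and 8 for JQ high, JQ medium, DCCO high and DCCO medium dose. An estimated correlation gave 2, 0, 0 and 0. Fry gave 0, 0 and 1 for the last 3. No filter gave 2 for JQ medium and 0 for DCCO high dose, blocks 4 and 1, the Z-linked covariate 2 for JQ medium dose, leaving out libraries with other-tissue markers 2 and those with number 6 in DCCO high dose 5, and the column number 2 for DCCO medium dose. The cause was not tested.

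Leaving out single libraries gave 303 to 659 for JQ high dose (control 1 303, 2 347, 4 309, high 5 340), 0 to 0 for JQ medium dose, 166 to 391 for JQ high against medium dose (medium 2 174, 3 168, 4 166, 5 181, high 3 180), 2 to 14 for DCCO high dose (control 1 14, control 3 2, unnumbered control 3, medium 1 to 4 2 each, medium 5 3, high 1 8, high 2, 3 and 4 2 each), 6 to 16 for DCCO medium dose (high 1 16), 0 to 1 for DCCO high against medium dose (control 3 1), 126 to 275 for the species difference at the high dose (lowest without DCCO high 3, highest without JQ high 2) and 0 to 1 at the medium dose (JQ high 5 or the unnumbered DCCO control 1). Shared by doses were 0 to 0 in JQ and 2 to 5 in DCCO (high 1 5).

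Lists called ranged from 3 to 7 for JQ high dose (high 2 7), 1 to 6 for JQ medium dose (control 1 2, 2 and 3 5 each, 5 3; medium 1 2, 2 and 3 3 each, 4 4, 5 6; high 1 and 5 3 each), 0 to 6 for DCCO high dose (controls 1 and 3 5 each, unnumbered 4; high 1 6, 3 4, 4 0) and 5 to 11 for DCCO medium dose (medium 5 5). Depth was not varied, so what it limits was not tested. Of planted 2-fold changes 56% were called at the size of JQ high dose and 69% at that of DCCO high dose.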

Other observations

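No test reported in this part was chosen after the result was seen, except the values of other-tissue genes, which were picked on seeing them. The features raised by the high dose in JQ were tested as a set in DCCO, on the hypothesis that both species respond alike below the threshold. They did not rise there: camera gave p 0.406, 0.427 with an estimated correlation, and 104 of 256 features (40.6%) lay above 0, with a median log2 fold change of -0.04 against 1.03 in JQ.

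JQ medium dose replicate 1 held MYL3 at 53.4, MYL2 at 35.4, TTN at 31.8 and TNNT2 at 20.1 CPM of its total, against at most 7.88, 6.69, 4.45 and 5.23 in the other JQ libraries. JQ control replicate 2 held GCG at 44.8, CELA3B at 18.4 and INS at 3.35 CPM, against at most 0.260, 8.83 and 0.0866. SLC12A1, a kidney gene, stood at 45.3 CPM in JQ high dose replicate 1, at a mean of 0.967 in the other high dose libraries and at 38.3 in controls.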
